A study of Mus musculus with 9 samples.

How the data were processed

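The series measured where 1 histone mark lies in the genome of mouse bone marrow cells, which the series' design text calls leukemia cells. The mark is H3R2me2a, asymmetric dimethylation of arginine 2 of histone H3, which the enzyme PRMT6 deposits. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done with an H3R2me2a antibody on wild-type cells, on cells without Prmt6 and on cells without Igf2bp2, a gene for a reader protein of m6A-modified RNA. Per the labels, the cells were cultured with interleukin 3, interleukin 6 and stem cell factor before fixation with formaldehyde and sonication. The 9 samples were 2 H3R2me2a libraries and 1 input library per genotype. A peak list came with each of the 6 H3R2me2a libraries, and the 3 input libraries were not analysed here. Nothing in the labels says whether the 2 libraries of a genotype came from separate animals or cultures, so every spread below is the spread between these libraries and may be technical. The WT libraries differed in their relative peak density on chromosomes X and Y (0.185 and 0.382 in replicate 1, 1.27 and 0.00923 in replicate 2), so these are not taken as repeats of the same cells.

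The submitters' processing notes name bcl2fastq 2.17, Trim Galore, HISAT2, MACS2 2.1.0, bedtools and the genome build mm10, without their settings or order. Each list held the peaks of 1 library, not of pooled replicates, and no peaks overlapped within a list. In the deposited lists, each peak had the fold enrichment at its summit, a ratio of signal to background. Each peak also had the -log10 of its p-value and of its q-value as the authors' peak caller gave them. The summit pileup, a coverage signal in fragments, stood in a companion table per the file headers, and its positions and fold enrichments equalled those of the peak list for every peak. These scores are the authors' and belong to their own list, so they were used here to describe, rank or filter peaks within a list.

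The background behind the fold enrichment was recovered from the values. In each list, fold enrichment equalled the pileup plus 1 divided by the background plus 1, with the same background for every peak of the list. No background that varied along the genome, local or from an input, is therefore visible within a list. Whether an input set the level of a list's background cannot be told from these values. Pileups were whole numbers in the wild-type and Prmt6KO lists. In the Igf2bp2KO lists they were multiples of 0.277 and 0.302, so the authors' values there are fragments scaled down. Before division by these steps, which gave fragments again, the background was 0.4021 and 0.4023 in these lists. In fragments, the background was 1.46 and 1.44 in wild type, 0.737 and 1.21 in Prmt6KO, and 1.45 and 1.33 in Igf2bp2KO. The lowest summit listed held 4 and 4 fragments in wild type, 2 and 3 in Prmt6KO, and 8 and 7 in Igf2bp2KO. The largest p of any listed summit was 0.0387, and a summit 1 pileup unit lower would have had a p of 0.0581 or more in each list, so the lists behave like a cutoff on the unadjusted p between these values. The total number of reads per library is not given in the sources used here, and the background in fragments is the measure of depth that the lists carry.

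Peaks on chromosomes 1 to 19 and X were compared. Groups were taken from the sample titles. Overlap meant at least 1 shared bp. Gene positions came from the RefSeq gene table of assembly GRCm38.p6, which is the build mm10, and 21631 protein-coding genes on these chromosomes entered. That table gives the start and end of each gene without strand, exons or transcripts. The planned promoter window at the gene 5' end was therefore replaced by 1 kb either side of both gene ends, called the gene-end window here. Exon and intron classes were replaced by gene-end window, gene body and intergenic. A gene was called in a group when a peak overlapped its gene-end window in both libraries, and absent when no peak did in either library. A gene was counted as lost when it was called in wild type and absent in a knockout, and as gained in the opposite case.

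Peak number and covered length were compared on the log2 scale with two-sided exact permutation tests of 2 libraries against 2, whose 6 splits allow no p below 0.333. Shares of peaks are given with Wilson intervals of 95%, which cover counting error alone. Overlaps and gene counts were set beside 100 circular shifts of each list along its chromosomes, a comparison whose smallest two-sided p is 0.0198. Shared loss and 20 gene lists were tested with two-sided Fisher's exact tests. The 140 list tests were adjusted together by the Benjamini-Hochberg method with a threshold of 0.05. Genes are not independent replicates, and these tests compare libraries.

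The following were fixed before the data were examined: the groups, the tests, the gene lists and the rule for the genes named. The rule names Prmt6, Igf2bp2 and Mfsd2a in each library. For each knockout it names the 12 lost and 12 gained protein-coding genes with the highest enrichment, ranked by the lower of the 2 libraries, leaving out predicted genes with Gm or Rik symbols. It also names up to 4 lost or gained members of each list, and members of the PRMT, IGF2BP and lipid lists kept in all groups, of which there were 0. For lack of strand, the region of the study's genes was the gene with 5 kb on both sides, in place of the upstream side alone. Other genes or regions named were chosen after their values were seen. The alternatives fixed with them were stricter q and fold thresholds, all chromosomes, each library left out, a 50% overlap, lists of equal length, peaks within 500 bp merged, a replicate block, a window of 2.5 kb and the entire gene body. Chosen after seeing the data were a q of at most 0.05, enrichment of at least 6 times each library's own background in fragments, the lists without a segment of chromosome 2, and chromosomes 1 to 19 alone. For the enrichment of at least 6 times, fragments plus 1 were divided by the background plus 1. The added 1 makes this threshold a higher multiple of the background itself where the background is low, as in Prmt6KO. Regional peak density was scanned in bins of 0.5 Mb with a likelihood ratio for intervals of at least 5 Mb. Random placement of 200 bp fragments at each library's background was simulated to count the peaks that chance alone gives.

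The steps were tested on simulated data. The overlap step recovered 100% of planted overlaps among 19989 peaks, and the gene step recovered 99.0% of planted losses among 21631 genes. The list test called the ribosomal protein list in 8.00% of 50 runs when its rate was 2 times that of other genes, in 72.0% at 4 times and in 100% at 8 times. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.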

Results

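Peak lists of H3R2me2a ChIP-seq from 3 genotypes of mouse leukemia cells were compared: wild type (WT), Prmt6 knockout (Prmt6KO) and Igf2bp2 knockout (Igf2bp2KO), with 2 libraries each. The series title places the experiment in a study of a PRMT6 and MFSD2A axis in leukemia stem cells. The comparisons ask what happens to the mark without the enzyme that writes it, or without the RNA-binding protein IGF2BP2. The WT lists held 162454 and 133960 peaks, the Prmt6KO lists 812414 and 430225, and the Igf2bp2KO lists 961 and 1221. The depth visible in the lists, the background per library, ran from 0.737 to 1.46 fragments. WT replicate 1 stood apart on the sex chromosomes. Relative to its other chromosomes it had a peak density of 0.185 on X and 0.382 on Y, where WT replicate 2 had 1.27 and 0.00923 and the Prmt6KO libraries had 0.956 and 1.22 on X and 0.0153 and 0.0171 on Y.

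The study's own genes came first. At Mfsd2a, which encodes a transporter of lysophospholipids carrying docosahexaenoic acid (chromosome 4, 122946850 to 122961194), neither WT list and neither Igf2bp2KO list held a peak within 5 kb of the gene. The Prmt6KO lists held 6 and 3 peaks there, and the mean peak density of those lists gives 7.69 and 4.07 for a region of this length, against 1.54 and 1.27 in WT and 0.0091 and 0.0116 in Igf2bp2KO. Their summits reached 4 and 5 fragments, none had a q of 0.05 or below, and no replicate 1 peak overlapped a replicate 2 peak. By the gene-end rule Mfsd2a counted as gained in Prmt6KO, with a fold enrichment of 2.30 in replicate 1 at 122960030 to 122960229 and of 2.26 in replicate 2 at 122946694 to 122946893, which are opposite ends of the gene.

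At Prmt6 itself (chromosome 3, 110246104 to 110250999), WT replicate 1 had 4 peaks within 5 kb and WT replicate 2 had 0. The Prmt6KO libraries had 7 and 4, of which 4 and 0 lay in the gene, and the Igf2bp2KO libraries had 0 each. Mean density gives 0.941 and 0.776 in WT, 4.71 and 2.49 in Prmt6KO, and 0.00557 and 0.00707 in Igf2bp2KO. At Igf2bp2 (chromosome 16, 22059009 to 22163299) the WT libraries had 4 and 3 peaks, Prmt6KO had 30 and 14, and Igf2bp2KO had 0 and 0. Mean density gives 7.22 and 5.96, 36.1 and 19.1, and 0.0427 and 0.0543 for this region. The counts were thus below that expectation in the WT and Prmt6KO libraries alike, and 0 is uninformative in Igf2bp2KO. The peak at 22158207 to 22158479 in WT replicate 1, with 11 fragments and a fold enrichment of 4.88, was the single one at these 3 genes with a q below 0.05. The extent of the deleted parts is not given in the sources used here, and a peak list at background density does not check the genotype labels.

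**Figure D1:**
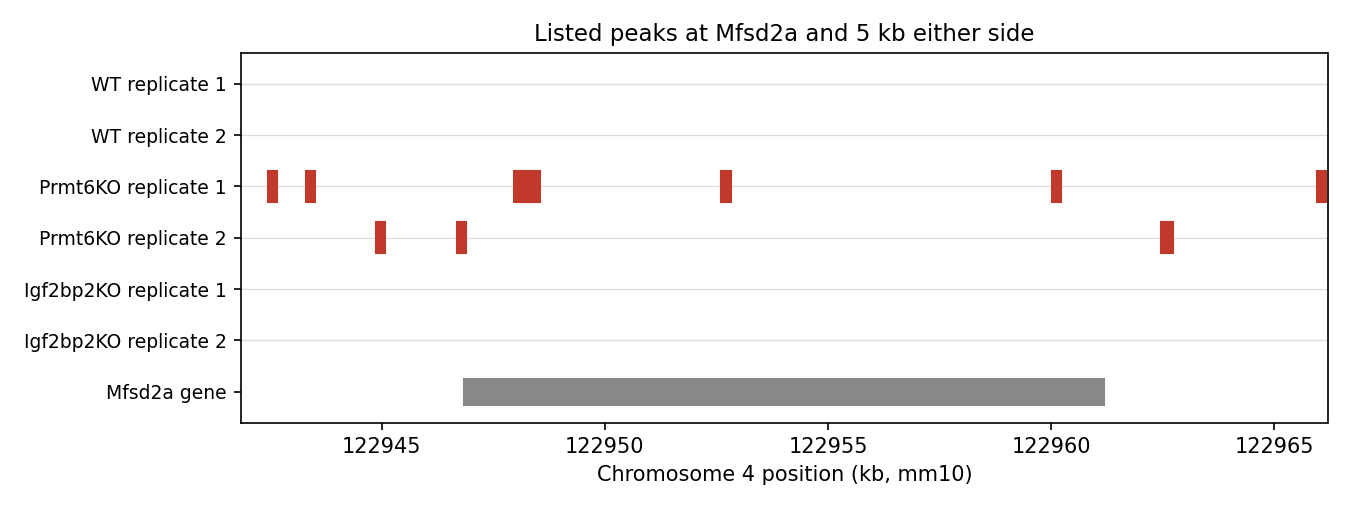
Peaks listed at Mfsd2a and 5 kb either side on chromosome 4, in kb of mm10. Each row is 1 library, each coloured box 1 listed peak and the grey box the gene; the Prmt6KO libraries hold 6 and 3 peaks, none of them overlapping between replicates, and the other 4 libraries hold 0.

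Prmt6KO lists were longer than WT lists. The mean peak number was 621300 ± 270200 (SD, n = 2) in Prmt6KO and 148200 ± 20150 (SD, n = 2) in WT, a difference of 2.00 on the log2 scale or 4.01-fold. The peaks covered 228.5 and 119.3 Mb in Prmt6KO and 43.8 and 36.5 Mb in WT, with mean widths of 281 and 277 bp against 270 and 272 bp. The exact permutation p was 0.333 for both quantities, the smallest that n = 2 per group allows. The difference was smaller among stronger peaks, by an amount that depended on the threshold. At a fold enrichment of at least 4, WT had 4957 and 2722 peaks and Prmt6KO 15258 and 5784, a log2 difference of 1.36 (exact permutation p = 0.333, the smallest possible), and 1.23 for covered length. At a q of 0.05 or below, WT had 4957 and 2722 peaks and Prmt6KO 4034 and 5784, a log2 difference of 0.40 (exact permutation p = 0.667). At 6 times each library's own background, WT had 366 and 194 and Prmt6KO 292 and 313, a log2 difference of 0.18. That threshold asks a higher multiple of the background itself in Prmt6KO, where the background was lower.

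Igf2bp2KO lists were shorter than WT lists. The mean was 1091 ± 183.8 peaks (SD, n = 2), a log2 difference from WT of -7.09, so that WT lists were 136-fold longer. They covered 0.458 and 0.548 Mb, with mean widths of 477 and 448 bp (exact permutation p = 0.333, the smallest possible). At a q of 0.05 or below 105 and 93 peaks remained, a log2 difference from WT of -5.22. Counted in fragments at 6 times each library's own background, Igf2bp2KO had 432 and 386 peaks, more than either WT library. The log2 difference turned to 0.62. Covered length at this threshold stayed lower than in WT, with a log2 difference of -0.50. Between 15 and 16 Mb of chromosome 5 alone, Igf2bp2KO held 127 and 96 of these peaks and WT 43 and 0.

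**Figure D2:**
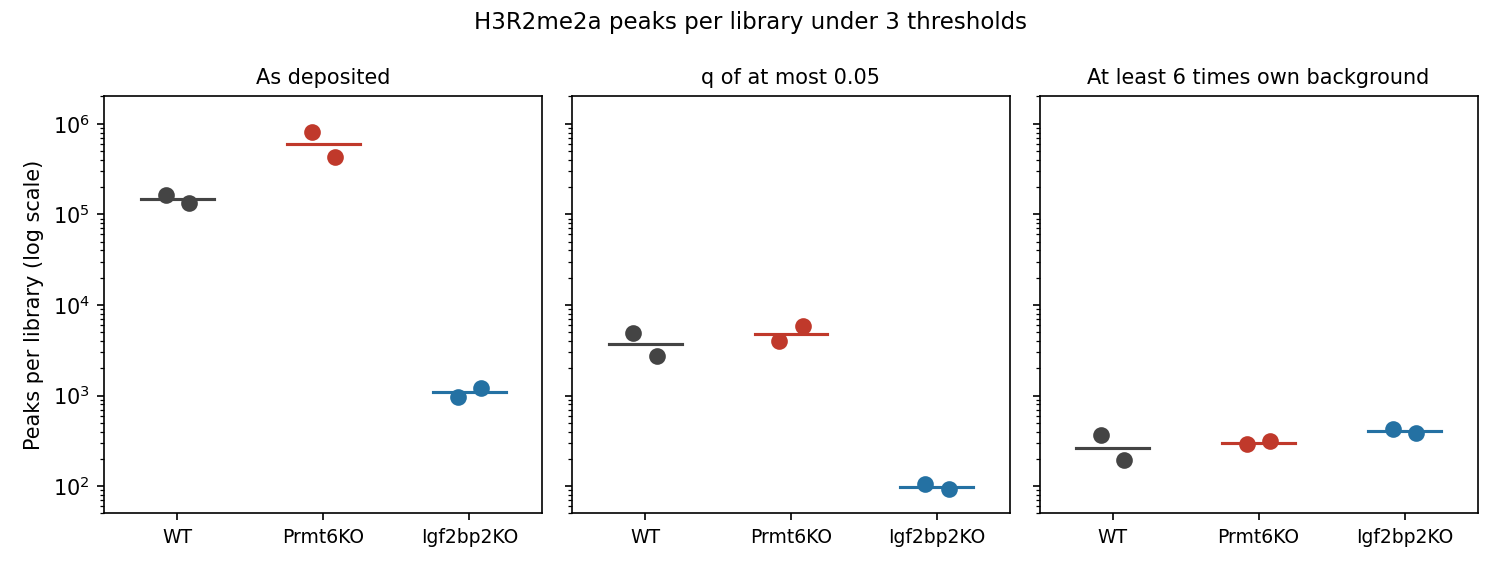
Peaks per library on a log axis in the 3 genotypes, as deposited, at a q of at most 0.05, and at 6 times or more of each library's own background in fragments. Each point is 1 library and each line the geometric mean of 2; the deposited numbers run from 961 to 812414, and those of the right panel from 194 to 432.

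The peaks of the longer lists lay mainly outside genes. Of the summits, 60.9% and 62.0% were intergenic in WT, 58.6% and 62.6% in Prmt6KO, and 66.0% and 68.6% in Igf2bp2KO, and 58.6% of the genome was in this class. Gene-end windows took 2.73% (95% Wilson interval 2.65 to 2.81) and 2.29% (2.21 to 2.37) of WT peaks, and 3.07% (3.03 to 3.10) and 2.38% (2.34 to 2.43) of Prmt6KO peaks, where 3.05% of the genome lay in such windows. WT peaks thus met gene ends 0.895 and 0.750 times as often as the windows' share of the genome. A peak counted here at any overlap, which raises its share against a share of bases. Of summits, 2.37% and 1.985% in WT and 2.69% and 2.09% in Prmt6KO lay in such windows, and 9.05% and 5.815% in Igf2bp2KO. Igf2bp2KO peaks met gene ends more often than WT peaks, at 9.99% (8.25 to 12.05) and 6.55% (5.30 to 8.08). The mean share was 2.51% ± 0.313 in WT, 2.72% ± 0.484 in Prmt6KO and 8.27% ± 2.43 in Igf2bp2KO (SD, n = 2). The exact permutation p was 0.667 for Prmt6KO and 0.333 for Igf2bp2KO against WT. Among peaks at 6 times or more of their own background, the share was lower in both knockouts than in WT, with differences of -1.58 percentage points in Prmt6KO and -1.31 in Igf2bp2KO. The Prmt6KO difference also turned without WT replicate 2 (-0.00522) and without Prmt6KO replicate 1 (-0.125).

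Replicates shared few peaks where lists were long. Past stricter thresholds they shared more in WT and Igf2bp2KO, but in Prmt6KO only at the strictest. In WT, 6.06% of the peaks of replicate 1 overlapped a peak of replicate 2, and shifted lists gave 2.80%. In Prmt6KO the share was 11.5% with 9.29% after shifting, and in Igf2bp2KO 56.2% with 0.102% after shifting (each permutation p = 0.0198, the smallest that 100 shifts give). Counted from replicate 2, the shares were 7.34% in WT, 21.6% in Prmt6KO and 43.7% in Igf2bp2KO, with 3.38%, 17.4% and 0.111% after shifting. At 6 times or more of the own background, the mean overlap was 49.1% in WT, 53.3% in Prmt6KO and 54.4% in Igf2bp2KO. The Prmt6KO mean was 16.5% among all peaks, 10.8% at a fold of at least 4 and 14.3% at a q of 0.05 or below. The shared bases were 2.94% of the union in WT, 4.57% in Prmt6KO and 34.5% in Igf2bp2KO.

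A set of 9852 WT replicate 1 peaks overlapped a peak of WT replicate 2, and these replicated peaks were followed into the knockouts. In Prmt6KO, 39.5% and 38.6% of them overlapped a peak, against 15.5% after shifting, and 2481 were present in both libraries while 4640 were present in neither. In Igf2bp2KO, 6.19% and 7.08% overlapped a peak, against 0.045% after shifting, and 8935 were present in neither library. With all peaks of a single WT library in their place, 17.1% (replicate 2) and 18.5% (replicate 1) overlapped a Prmt6KO peak, and 0.532% and 0.493% an Igf2bp2KO peak. Among the 131 replicated WT peaks at 6 times or more of the background, the share found at the same enrichment was 74.4% ± 8.10 in Prmt6KO and 75.2% ± 0.540 in Igf2bp2KO (SD, n = 2). Of these 131 regions, 17 and 23 were found in neither library of the respective knockout.

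At gene ends, 770 genes had a WT peak in both libraries, where shifted lists gave 1004 ± 43.8 (SD over 100 shifts). Prmt6KO had 6274 such genes, with 8627 after shifting, and Igf2bp2KO 45, with 0.1 after shifting. In Prmt6KO 92 genes were lost and 4032 gained, and shifted lists gave 106 and 5269. The losses were within the range of the shifts (permutation p = 0.238), and the gains were fewer than in any shift (permutation p = 0.0198, the smallest possible). The shifts moved every list, WT included, and gave more called genes in WT and Prmt6KO than observed. Lost and gained counts thus stand beside unlike totals, and fewer gains need not mean a lower rate of gain. In Igf2bp2KO 716 of the 770 WT genes were lost and 0 genes were gained. Shifts gave 1001 losses among their 1004 WT genes. With lists of equal length, Prmt6KO lost 358 genes and gained 367, and Igf2bp2KO lost 3 and gained 1. Igf2bp2KO losses were 43 at a q of 0.05 or below, 29 at a -log10 q of at least 5 and 27 at a fold of at least 4. At a q of 0.05 or below the counts fell to 0 lost and 5 gained genes in Prmt6KO. The 5, named after their values were seen, were Amy2a4, Gm38510, Mup19, Speer4d and Vmn1r155, of which Amy2a4, Mup19, Speer4d and Vmn1r155 belong to multigene families whose copies can share reads. With a library left out, its group was called from the 1 remaining library, a looser rule under which losses and gains can only rise or stay. With WT replicate 1 or 2 left out, Prmt6KO losses were 375 and 561 and Igf2bp2KO losses 2743 and 3924. With Prmt6KO replicate 1 or 2 left out, losses were 322 and 174, and gains rose to 11170 without replicate 2.

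The Prmt6KO losses with the highest WT enrichment were shallow. Eif2s1, a subunit of translation initiation factor 2 (chromosome 12, 78862072 to 78887010), led with fold enrichments of 4.06 and 3.69 and summits of 9 and 8 fragments. Next came the shared end of Emc3 and Fancd2, the latter a Fanconi anemia DNA repair gene, with 4.47 and 3.28 (113530942 to 113531171 on chromosome 6 in replicate 1). Jrkl, Olfr1054, Tmed10, the shared end of Ugp2 and Vps54, Bex6, Lrrfip2, Cep152 and Ermn completed the list. Their lower fold enrichments were between 2.87 and 3.28, and no peak of these 12 genes had a q of 0.05 or below in both WT libraries. At Ugp2 and Vps54 the peaks of the WT libraries overlapped (21320768 to 21321026 on chromosome 11 in replicate 1). At the other 10 genes they lay at different positions within the gene-end windows. Rpl30 and Rpl7 were the lost members of the ribosomal protein list.

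The Prmt6KO gains with the highest enrichment were Vmn1r155, a vomeronasal receptor gene (chromosome 7, 22658018 to 22658941), with fold enrichments of 4.61 and 4.98, and Mup19, a major urinary protein gene, with 4.61 and 4.07. Mpp1, the shared end of Nit1 and Pfdn2, AF067063, Gfral, Olfr868, Rbms2, Adam26b, Cntn4 and Drc7 followed, with lower fold enrichments between 3.46 and 4.03. Of these 12 genes, Vmn1r155, Mup19, Nit1, Pfdn2 and Rbms2 had overlapping peaks in the Prmt6KO libraries. Gains at the following genes of leukemia and blood formation had summits of 3 to 5 fragments. Myc, the proto-oncogene transcription factor, had 2.88 and 2.72; Kit, the stem cell factor receptor, 2.30 and 2.72; Hoxa7 2.30 and 2.26; Runx1, a regulator of blood stem cell formation, 2.88 and 2.26; and Mpo, the myeloperoxidase of granulocytes, 2.88 and 2.72. Genes that blood cells do not use were gained at like values, such as the adipocyte hormone gene Adipoq with 3.46 and 2.72, and the keratin gene Krt20 with 2.88 and 2.72.

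Among the 716 genes lost in Igf2bp2KO, Sp110, a nuclear body protein gene of the interferon response (chromosome 1, 85570735 to 85610850), had the highest WT enrichment with 5.28 and 5.33, and Prmt6KO lists held peaks of 5.18 and 5.89 there. Sprr2a2, an epidermal envelope gene, had 7.72 and 4.51, and Zfp979 5.69 and 4.51. Chil4, Eif2s1, Olfr788, Sspn, Zfp534, Zfp984, AA792892, Mucl2 and Abca12 followed with lower values between 3.28 and 3.69. Igf2bp3, a paralog of the deleted gene, counted as lost with 2.84 and 2.87, and so did Ythdf3, an m6A reader gene, with 3.25 and 2.46. The myeloid genes Cd14 and Csf1r, the latter encoding the receptor of macrophage colony stimulating factor, and Angpt1 had WT summits of 5 to 7 fragments. Summits at Igf2bp3 and Ythdf3 also held 5 to 7 fragments. The lowest summits listed in Igf2bp2KO held 8 and 7 fragments, so regions of this height could hardly be listed there. Their absence is no evidence that the mark was lost. Counted in fragments at 6 times the own background, 5 genes were lost (Elobl, Gm40364, Gm40367, Ugt1a6b and Ugt1a8) and 3 gained (4930467E23Rik, Gm21083 and Speer4d), all named after their values were seen.

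Overlap of loss between the knockouts was nearly forced, because 716 of the 770 WT genes were absent in Igf2bp2KO. All 92 genes lost in Prmt6KO were also absent in Igf2bp2KO, where 85.6 were expected from independent loss among the 770 WT genes (Fisher's exact p = 0.00160). The Fisher test counts genes that share a peak, such as several Ugt1a genes, as separate. Shifted knockout lists against the observed WT lists gave 83.5 ± 8.47 (permutation p = 0.376), so the overlap was within the range of the shifts. Independent lists among all 21631 genes give 3.04, which is not a like comparison, because both losses were drawn from the 770 WT genes. Part of any excess may come from the shared WT libraries, which were not split between the knockouts. The call ended with windows of 2.5 kb (log2 odds ratio 1.36, Fisher's exact p = 0.633), with gene bodies (0.17, p = 1.00), at a -log10 q of at least 5 (0.17, p = 1.00) and at 6 times the own background (1.99, p = 0.221). At a q of 0.05 or below and at a fold of at least 4, Prmt6KO lost 0 genes, so sharing could not be tested.

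No gene list passed the test against other genes. Of 140 Fisher's exact tests over 20 lists, 0 passed the threshold after Benjamini-Hochberg adjustment (lowest adjusted p = 0.737), and 6 had an unadjusted p under 0.05. With windows of 2.5 kb 4 tests passed, for olfactory receptor and keratin genes. With entire gene bodies 15 passed, for ribosomal protein, histone, olfactory receptor, keratin and mitochondrial respiratory genes. In these 15, shares of called and gained genes were lower than in other genes, and shares of lost genes higher. Gene length was not matched, so they cannot be told from an effect of length. Of the PRMT family, 0 of 9 genes had a gene-end peak in both libraries of any genotype. Of the m6A list, 2 of 16 genes were called in WT (Igf2bp3 and Ythdf3) and 3 were gained in Prmt6KO (Fto, Ythdf1 and Zc3h13). Lipid transport and docosahexaenoic acid genes had 0 of 27 called in WT, and 7 of the 22 absent in WT were gained in Prmt6KO, or 31.8% against 25.8% of other genes (Fisher's exact p = 0.475), including Abcg1, a cholesterol exporter, and the fatty acid transporter Cd36. The leukemia stem cell and HOXA list had 0 of 20 called in WT and 6 of 15 gained in Prmt6KO, or 40.0% against 25.8% of other genes (Fisher's exact p = 0.237, adjusted p = 1.00).

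Lists for other cell types and processes had more called genes in the longer Prmt6KO peak lists than in WT. Called in both WT libraries were 1 of 20 hematopoietic stem cell genes, 2 of 25 myeloid, 1 of 18 erythroid and megakaryocyte, 0 of 15 B cell, 0 of 15 T and NK cell, and 0 of 16 stromal and endothelial genes. In Prmt6KO the counts were 6, 7, 5, 3, 4 and 5, and 29.02% of other genes were called there. Of 28 cell cycle genes, 38 Wnt genes, 25 H3K4 methylation and Polycomb genes, 18 glycolysis genes and 19 apoptosis genes, WT had 0, 1, 1, 0 and 0 called and Prmt6KO 8, 6, 6, 5 and 6. Ribosomal protein genes had 3 of 84 called in WT and 24 in Prmt6KO, and mitochondrial respiratory genes 0 and 26 of 84. Of 67 histone genes 3 and 11 were called, and of 109 keratin genes 1 and 21. Igf2bp2KO had 0 called members in each of the 20 lists.

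Olfactory receptor genes, expressed mainly in sensory neurons of the nose, had the lowest p of the list results. In WT 55 of 1110 were called, or 4.95%, against 3.48% of other genes (Fisher's exact p = 0.0125, adjusted p = 0.737). In Prmt6KO 13 of these 55 were lost, or 23.6%, against 11.05% of other genes (Fisher's exact p = 0.0151, adjusted p = 0.737). With windows of 2.5 kb the WT difference kept its direction, at 18.1% against 13.05% (Fisher's exact test, adjusted p = 0.000244). With gene bodies in place of gene ends it turned, to 6.94% against 40.3% (Fisher's exact test, adjusted p = 1.76e-134). A longer gene has more room for a peak, and gene length was not matched. The turn with gene bodies therefore cannot be read as a difference of the mark. The loss in Prmt6KO was 8.96% against 1.01% with windows of 2.5 kb (Fisher's exact test, adjusted p = 3.31e-08). Without WT replicate 1 it was 21.0% against 12.6%. Neither was repeated without the chromosome 2 segment described next, which held 9 of the 13 receptor genes lost in the main call. With single libraries in place of replicated calls the list passed the threshold in WT, in the same direction in each library. Alone, WT replicate 2 had 24.5% against 12.3% of other genes (Fisher's exact test, adjusted p = 8.94e-25), and WT replicate 1 had 23.3% against 18.2% (adjusted p = 0.00340). The Prmt6KO libraries went opposite ways. Replicate 2 alone had 44.8% against 38.0% (Fisher's exact test, adjusted p = 0.00107), and replicate 1 alone had 61.6% against 73.1% (adjusted p = 1.18e-13).

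Prmt6KO peak density was low along a segment of chromosome 2. Between 53.5 and 120 Mb, a segment with 634 protein-coding genes that includes Spi1, the gene of the myeloid master regulator PU.1 (91082374 to 91115759), peak density in Prmt6KO was 0.494 and 0.333 times that of the 20 Mb on either side. In WT the same ratio was 1.03 and 1.05. Of WT-called genes, 18 of 33 inside the segment were lost in Prmt6KO, or 54.5%, against 74 of 737 elsewhere, or 10.0%. The segment held 9 of the 13 lost olfactory receptor genes, among them Olfr1054, Olfr1130, Olfr1295 and Olfr1308. Outside it, 4 of 35 olfactory receptor genes and 70 of 702 other genes were lost (Fisher's exact p = 0.772). The segment was found by scanning the data for low Prmt6KO density, so more loss inside it follows from the choice and was not tested. Scanned alone, replicate 1 placed its start at 40500001 with a ratio to WT of 0.450, and replicate 2 at 53500001 with 0.295, both with the end at 120000000. A shorter stretch of chromosome 4 also had a low ratio to WT in both libraries. It ran from 143500001 to 148500000 with 0.365 in replicate 1 and from 145000001 to 150000000 with 0.497 in replicate 2. Whether WT was high or Prmt6KO low there was not examined. The scan returns the most extreme interval of every chromosome, and replicate 1 had a ratio of 2.18 on chromosome 5.

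**Figure D3:**
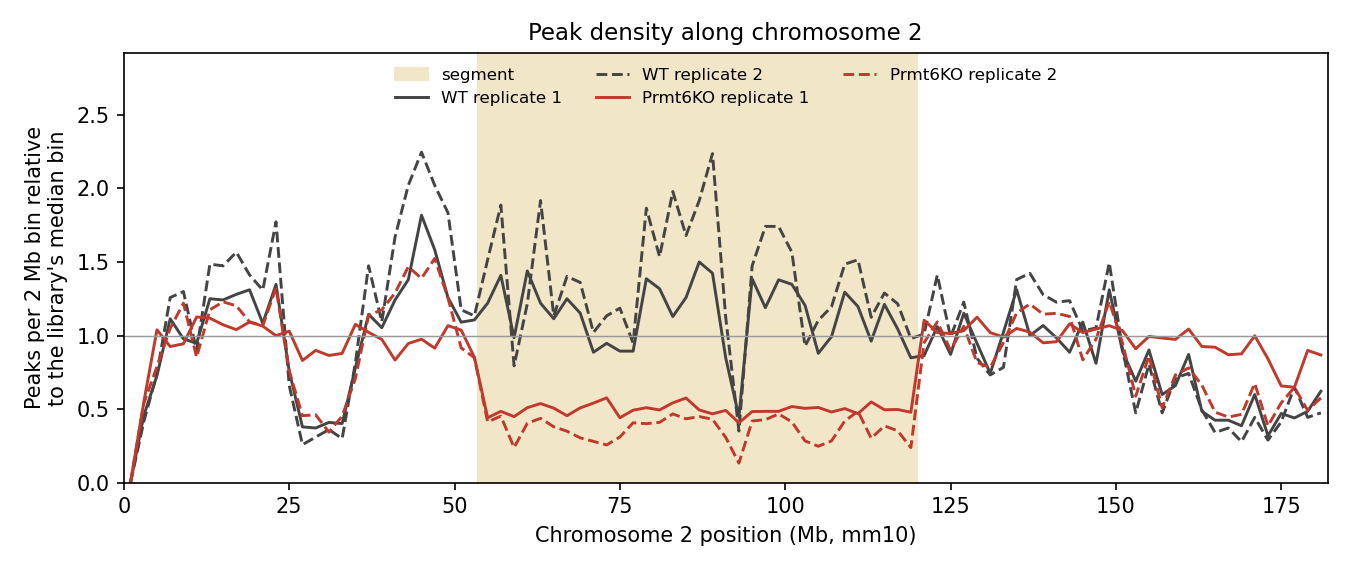
Peak density along chromosome 2 in bins of 2 Mb, relative to the median bin of each library, for the WT and Prmt6KO libraries. Lines are single libraries and the shaded band is the segment from 53.5 to 120 Mb, where both Prmt6KO lines lie below both WT lines in the bins from 54 Mb on, except that from 92 to 94 Mb Prmt6KO replicate 1 lies above WT replicate 2; Igf2bp2KO lists hold too few peaks to draw.

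The strongest peaks lay in the same places in all 6 lists. Each list's 10 strongest peaks overlapped a peak in all 5 other lists. The peak at 98666070 to 98667526 on chromosome 2, in no annotated gene, of WT replicate 1 and its counterparts in the other lists held 398, 390, 388, 397, 394 and 394 fragments. In WT replicate 1, others lay at 35304874 to 35305734 on chromosome 9, at 19415569 to 19419701 on chromosome 14, at 3109709 to 3110230 on chromosome 12, and in Chl1 on chromosome 6. In Prmt6KO replicate 2, the ribosomal RNA unit Rn18s-rs5 on chromosome 17 was among them. At gene ends, 41 genes had a peak in all 6 libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123366927 to 123462675), had fold enrichments of 28.9 and 11.1 in WT, 25.3 and 43.5 in Prmt6KO, and 8.03 and 6.95 in Igf2bp2KO on those lists' scaled values. Sfi1, Tmem267, Wls, Duxf3 and 9 Ugt1a genes, 7 of which share the gene end at 88220002 of chromosome 1, were also among the 41. These regions were chosen after their values were seen.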

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

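The tests weighed here were chosen only after the results they bear on were seen, except the peak number at a -log10 q of at least 5. The knockouts moved in opposite directions from WT in peak number, by 2.00 on the log2 scale in Prmt6KO and by -7.09 in Igf2bp2KO, each in both libraries, and this difference was not tested. Chromosome Y, which the comparisons leave out, held 2227 peaks in WT replicate 1, 40 in WT replicate 2, 432 and 251 in Prmt6KO, and 1 and 2 in Igf2bp2KO.

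The first pattern is peak number, higher than WT in Prmt6KO and lower in Igf2bp2KO. Differences in depth behind a single nominal p threshold may account for the Prmt6KO excess. At 6 times each library's own background the log2 difference was 0.18. That threshold is stricter for the lower backgrounds of Prmt6KO, so this value does not isolate depth. Random placement at the observed backgrounds gave a 4.03-fold difference with peaks joined over 50 bp and 3.401-fold over 150 bp, where 4.01-fold was observed. Over 50 bp it gave 224100 and 210500 simulated WT peaks against 162454 and 133960 listed. For Prmt6KO it gave 1151000 and 665800 against 812414 and 430225 listed. Pileups scaled down before the threshold may account for the Igf2bp2KO deficit, since the log2 difference was 0.62 in fragments at 6 times the own background. Covered length stayed below WT there, at -0.50. Between 15 and 16 Mb of chromosome 5 alone, Igf2bp2KO held 127 and 96 of these peaks and WT 43 and 0. The 0.62 therefore does not show a general excess of peaks. A gain of marked regions without PRMT6 stays open, because depth and genotype cannot be told apart here: the log2 difference was 0.40 at a q of 0.05 or below (exact permutation p = 0.667) and -0.11 at a -log10 q of at least 5. A loss of weaker marked regions without IGF2BP2 also stays open, because 75.2% of strong replicated WT peaks were found in Igf2bp2KO while its lists hold no values for weaker regions.

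The second pattern is the low Prmt6KO peak density between 53.5 and 120 Mb of chromosome 2. A regional bias shared by WT and Prmt6KO was not visible in the WT ratios of inside to flanks, the lower of which was 1.03. The segment was chosen for its low ratio of Prmt6KO to WT, so a shared dip would hardly have been picked. The WT ratio is therefore no independent test, and Igf2bp2KO lists hold too few peaks to examine. Loss of 1 of 2 copies in part of the Prmt6KO cells is a candidate explanation. Under random placement the densities need a coverage of 70.0% and 70.8% of the flanks, which would correspond to 60.0% and 58.4% of cells. With peaks joined over 150 bp the coverage was 67.4% and 69.2%, or 65.1% and 61.5% of cells. Random placement over 50 bp gave more Prmt6KO peaks than were listed (1151000 and 665800 against 812414 and 430225). These percentages are therefore rough, and they do not test the explanation. Partial loss of chromosome 2 including Spi1 is known from radiation-induced mouse myeloid leukemia. Less of the mark along the segment without PRMT6 stays open, since no input value per region was used here, and the 54.5% of WT genes there without a Prmt6KO peak follows from how the segment was chosen and decides nothing. The segment was found by scanning these data, and its copy number was not measured.

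The third pattern is that the strongest peaks lay at the same regions in every genotype. Reads of many genomic copies placed on few reference copies may be involved, but this stays open: that all 10 strongest peaks of each list were found in every other list is the pattern itself, and copy number was not measured. Summits capped by 1 fragment kept per position and strand may account for the like height of the highest peak, with 398 fragments at most where a cap for fragments of 200 bp would be 400, and the other 9 of each list lay below that, at 98 to 360 fragments. A mark wholly dependent on PRMT6 is argued against for these strong regions, since 74.4% ± 8.10 (SD, n = 2) of strong replicated WT peaks were found in Prmt6KO. That holds only if the peaks are the mark, which the shared regions leave open.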

How the results depend on the processing

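The alternatives with a q of at most 0.05, with 6 times the own background, without the chromosome 2 segment and with chromosomes 1 to 19 alone were chosen after seeing the data. Log2 differences of peak number and covered length kept their direction under every alternative run, except those named next, but not their size: covered length in Prmt6KO fell from 2.05 to 0.02 with -log10 q of at least 5, to 0.45 with q of at most 0.05 and to 0.22 at 6 times the own background, and in Igf2bp2KO it was -2.56, -3.86 and -0.50. With 2 libraries per group no exact permutation of library labels can give a p below 0.333, and the cause of each change below was not tested. Gene-end shares are differences from WT in percentage points, overlap is the mean over both replicates, and shared loss is a log2 odds ratio. The window at any transcript 5' end was not run, for lack of transcripts in the gene table. Low background, from 0.737 fragments, limits what weak peaks can show.

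With -log10 q of at least 5, peak number turned in Prmt6KO (-0.11), as did gene-end shares (-1.66 in Prmt6KO, -6.68 in Igf2bp2KO). Replicate overlap was 47.9% in WT, 52.3% in Prmt6KO and 75.2% in Igf2bp2KO, and 69.9% and 17.1% of WT peaks were retained in Prmt6KO and Igf2bp2KO. Prmt6KO lost 5 genes and gained 1, Igf2bp2KO lost 29, and shared loss was 0.17. With a fold of at least 4, the Prmt6KO gene-end share was -1.06, and retention 72.9% and 14.4%. Overlap was 22.0% in WT, 10.8% in Prmt6KO and 61.5% in Igf2bp2KO. Prmt6KO lost 0 genes and gained 13, Igf2bp2KO lost 27 and gained 1, and with 0 losses the value of -0.42 for shared loss rests on the added pseudocount alone.

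With a q of at most 0.05, the Prmt6KO gene-end share was -0.463, and retention 67.2% and 8.33%. Overlap was 22.0% in WT, 14.3% in Prmt6KO and 67.0% in Igf2bp2KO. Prmt6KO lost 0 genes and gained 5, Igf2bp2KO lost 43, and the value of -3.27 for shared loss likewise says nothing of sharing. At 6 times the own background, peak number turned in Igf2bp2KO (0.62), as did gene-end shares (-1.58 in Prmt6KO, -1.31 in Igf2bp2KO). Overlap was 49.1% in WT and 53.3% in Prmt6KO, and retention 74.4% and 75.2%. Prmt6KO lost 5 genes and gained 1, Igf2bp2KO lost 5 and gained 3, and shared loss was 1.99.

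With lists of equal length, retention was 26.2% and 65.7%, Prmt6KO lost 358 genes and gained 367, and Igf2bp2KO lost 3 and gained 1. With an overlap of 50%, WT overlap was 4.61% and retention 37.0% and 8.57%. Retention in Prmt6KO was 40.3% on all chromosomes, 39.8% without the chromosome 2 segment and 38.1% on chromosomes 1 to 19. With windows of 2.5 kb, Prmt6KO lost 45 genes and Igf2bp2KO 2802, shared loss was 1.36 and 4 list tests passed. With gene bodies, the losses were 34 and 8209, shared loss was 0.17 and 15 list tests passed.

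With each library left out in turn, the Prmt6KO gene-end share ran from -0.125 to 0.558, retention from 17.1% to 39.5% in Prmt6KO and from 0.493% to 7.08% in Igf2bp2KO. Prmt6KO losses ran from 174 to 561 and gains from 4783 to 11170, Igf2bp2KO losses from 722 to 3924 and gains from 0 to 4, and passing list tests from 0 to 2. Genes of the reduced group were then called from the 1 remaining library, so losses and gains could only rise or stay. Retention without a WT library counted all peaks of the other, not replicated ones.

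The labels share replicate numbers but do not say that they pair libraries. Deviations of same-numbered libraries correlated across genes at 0.0026 between WT and Prmt6KO, -0.0033 between WT and Igf2bp2KO and 0 between the knockouts. With the replicate number as a block the differences stayed at 2.00 and -7.09 for peak number, 2.05 and -6.32 for covered length and 0.216 and 5.76 for gene-end share, with an exact permutation p of 0.5, the smallest possible, and no call changed.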

Other observations

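The regions below were chosen only after their values were seen, and no explanation is offered for them. Peaks at 6 times or more of the own background were counted per 1 Mb, and some of the highest counts follow. Between 3 and 4 Mb of chromosome 11, which holds Sfi1 among other genes, the lists held 26 and 20 in WT, 16 and 19 in Prmt6KO, and 29 and 22 in Igf2bp2KO. Between 15 and 16 Mb of chromosome 5, at the testis gene family members Speer4c and Speer4d, the lists held 43 and 0 such peaks in WT, 45 and 48 in Prmt6KO, and 127 and 96 in Igf2bp2KO. Between 20 and 21 Mb of chromosome 8, next to the beta-defensin gene Defb33, they held 62 and 47, 33 and 42, and 57 and 64. At the zinc finger genes between 147 and 148 Mb of chromosome 4, among them Zfp979 and Zfp984, they held 18 and 14, 12 and 17, and 20 and 18. Between 85 and 86 Mb of chromosome 1, at the interferon response genes Sp100, Sp110 and Sp140, they held 8 and 0, 10 and 4, and 8 and 1.

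WT replicates differed at several of these regions. WT replicate 2 held 0 such peaks between 14 and 15 Mb of chromosome 5, where WT replicate 1 held 15, and 4 between 94 and 95 Mb of X, where WT replicate 1 held 0. Relative peak density on X was 3.52 and 3.53 in Igf2bp2KO, from 49 and 97 peaks. This was not particular to X. In the same lists it was 25.4 and 14.7 on chromosome 8, 19.5 and 10.1 on chromosome 5, and 7.77 and 7.08 on chromosome 4.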
